A study of Mus musculus with 21 samples.

How the data were processed

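The matrices of UMI counts per gene and cell barcode that the authors deposited for 21 libraries were read as they stood, as unnormalised counts. The submitters name Cell Ranger, Seurat 3.0 and genome build mm10, and the role of Seurat is not given in the sources used here. Per the file headers the Cell Ranger version was 3.0.2 or 3.1.0 for some libraries, and for the others it is not given in the sources used here. Alignment settings, the cell calling setting and any ambient RNA step by the submitters are not given in the sources used here. The gene tables held 27998 or 31053 genes, and the 27514 genes shared by all libraries were used. Gene positions came from the annotation table of build mm10.

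Cells with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept, 144722 of 153337 barcodes. The lowest UMI count per barcode differed between the deposited lists, so a common minimum per tissue was tried as well: 1354 in heart, 1068 in blood, 2189 in marrow and 502 in LSK. Kept cells numbered 10546 at WT day 4, 3546 and 4961 with antibody, 7055 and 6498 in Nrf2-/- and 4999 at WT day 0 in heart. Blood held 4302, 2989, 1754 and 3097 in WT and 10762 and 10255 in Irf3-/-. Marrow held 3830, 2134 and 2307 in WT, 8790 and 12935 in Irf3-/- and 17008 and 13127 in Tet2-/-, and the LSK libraries 4975 and 8852. Total UMIs per library ran from 6.198 to 98.528 M (M for mega). In barcodes starting AAACC, the only ones examined, the next base defined sets A and B.

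Cells of each tissue were clustered with scanpy 1.11.5 and leidenalg 0.10.2 on log-normalised counts with both interferon lists and ribosomal, mitochondrial, immunoglobulin variable, sex-linked and interferon-induced family genes left out of the variable genes (up to 2000 variable genes, 30 components, 15 neighbours, resolution 1). Clusters were named from fixed marker sets, and a cluster with fewer than 3 raised markers, or with markers of another class among its leading genes, was left unnamed. Monocyte-like and macrophage-like heart clusters were pooled as mononuclear phagocytes. Doublets were kept in the main tests and removed in an alternative at 0.8% per 1000 cells by a score from simulated pairs, which marked from 1.43 to 13.61% of cells. Cells were not integrated across libraries, which leaves library-specific clusters as they are.

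Counts were summed per library and class with at least 20 cells. Groups were compared with edgeR 4.0.16 (TMM factors, low-count filter, quasi-likelihood F tests) in R 4.3.3 with limma 3.58.1, and p-values were adjusted by the Benjamini-Hochberg procedure within each comparison, with 0.05 as the limit. The SE of a log2 fold change is its size over the square root of F. Heart mononuclear phagocytes were fitted over 6 libraries with 2 residual degrees of freedom and heart neutrophils over 5 with 2. The MI tests used 7 libraries with 4, and the marrow genotype tests 7 with 3. The Irf3 tests used 8 in blocks of tissue and day with 3. The difference of changes used the same 8 without blocks, with terms for tissue, genotype, day and genotype by day, also with 3. A group of 1 library takes its spread from the other groups of the fit. DESeq2 1.42.0 was run as an alternative. Gene lists, 16 in number and fixed before the data were examined, were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, for lists of at least 3 measured members, adjusted over the lists. Members were also adjusted over the list alone.

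Genes were named by a fixed rule. It covers the targeted gene in every library of the classes tested, the 10 largest rises and falls among called genes with a mean log2 CPM of at least 5, and the 4 called members with the smallest adjusted p of each called list. It also covers Isg15, Ifit1, Ifit3, Irf7, Rsad2 and Cxcl10 always. Ribosomal protein, mitochondrial, unnamed, immunoglobulin variable and sex-linked marker genes were passed over. The report names a part of these genes for length. Among them, genes whose call held without any single library were preferred after the values were seen. Where a group had no count, the fold is given as at least the value that 3 counts over the group would give.

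The share of interferon list UMIs was taken per 10000 UMIs of a class and library with 95% Poisson intervals, which cover counting error only. Interferon-high cells were those with at least 3 list UMIs after thinning each cell to 500 UMIs, and at least 2, thinning to 1000 and no thinning were tried. The LSK libraries, 1 per time, were compared by CPM ratios with exact 95% intervals for genes of at least 50 CPM in either library, and list medians were set against 10000 random lists drawn from 20 expression bins. The median log2 ratio over all genes was 0.07.

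Each test was tested on simulated data made from the same libraries, with 200 changed genes. For a 4-fold change the percent found was 72 for antibody against WT day 4, 74 for Nrf2-/- against WT day 4, 75 for Nrf2-/- against antibody, 50 for WT day 4 against day 0 and 51 for antibody against WT day 0 in mononuclear phagocytes. For a 2-fold change it was 19, 13, 24, 5 and 9. In heart neutrophils it was 46, 73 and 61 at 4-fold and 4, 8 and 15 at 2-fold. For MI it was 83 in neutrophils and 94 in monocytes at 4-fold and 39 and 53 at 2-fold, and for Irf3 96 and 99, and 56 and 72. For the difference of changes it was 41 and 80 at 4-fold and 2 and 16 at 2-fold. For day 2 against day 0 in neutrophils it was 69 in WT and 88 in Irf3-/- at 4-fold, 20 and 14 at 2-fold, and in monocytes 94 and 99, and 42 and 60. For Tet2-/- against WT in neutrophils, monocytes and progenitors it was 82, 96 and 93 at 4-fold and 55, 65 and 58 at 2-fold. Against Irf3-/- it was 96, 99 and 99, and 64, 65 and 53. No changed gene was called in the wrong direction, and false calls ran from 0 to 13.

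Alternatives covered other scaling factors, no low-count filter, at least 1000 UMIs and 500 genes, at most 5% mitochondrial UMIs, macrophage-like clusters only, other sets of days and libraries, a block by replicate or day, and each library left out in turn. The common UMI minimum, the tests within a barcode set, the day 0 to day 2 tests within a genotype, the progenitor test, the removal of day 1 libraries and of doublets in the interferon share were added after the data were seen. Left out were ambient RNA removal, integration across libraries, splicing, and classes with too few cells for a test. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used beside these tools.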

Results

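Single-cell RNA counts were collected from 21 mouse libraries made with 10x Genomics droplets from immune cells of heart, blood and bone marrow, at steady state (day 0) and after myocardial infarction (MI). The heart held 1 wild-type (WT) library at day 0 and 1 at day 4. It also held 2 day 4 libraries after an antibody against the type I interferon receptor (Ifnar antibody) and 2 day 4 libraries from Nrf2-/- mice, which lack a regulator of antioxidant genes. Blood held 4 WT libraries, 1 each at days 0, 1, 2 and 4, and 2 Irf3-/- libraries, at days 0 and 2. Irf3 is a transcription factor that switches on type I interferon after nucleic acid sensing. Marrow held 3 WT libraries at days 0, 1 and 2, 2 Irf3-/- libraries at days 0 and 2, and 2 labelled Tet2-/-, for an enzyme that oxidises methylated DNA. Another 2 WT libraries, at days 0 and 1, were labelled LSK. By its usual meaning this is a sorted marrow population (lineage-negative, Sca-1-positive, Kit-positive), but the labels do not spell it out. The later library labelled Tet2-/- carried day 2 in its title and day 1 among its characteristics, so it was used only as after MI.

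Of 153337 deposited barcodes, 144722 passed the filter. Total UMIs in the heart were 86.1 M (M for 1e6) at WT day 4, 11.4 and 16.4 M in the antibody hearts, 98.5 and 49.4 M in Nrf2-/- hearts and 9.42 M at WT day 0. In blood they were 6.43, 6.95, 6.20 and 8.05 M in WT at days 0, 1, 2 and 4, and 49.1 and 45.2 M in Irf3-/-. Marrow libraries held 13.02, 11.9 and 12.1 M in WT, 59.8 and 90.5 M in Irf3-/- and 69.4 and 70.8 M in those labelled Tet2-/-. The LSK libraries held 35.0 and 62.9 M. Median UMIs per kept cell ran from 1039 in WT day 0 blood to 13020 in an Nrf2-/- heart.

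By barcode start, libraries fell into barcode sets A and B. Set A held the WT day 0 heart, both antibody hearts, all WT blood and marrow and the LSK libraries. Set B held the WT day 4 heart, both Nrf2-/- hearts and every library labelled Irf3-/- or Tet2-/-. Barcode set therefore ran together with group when antibody hearts were compared with WT day 4 or Nrf2-/- hearts, WT day 4 with day 0 hearts, and either marrow genotype with WT. Nothing in the labels shows that libraries came from separate animals, so p-values measure the spread between these libraries, which can be technical. No combination of tissue, day and genotype in blood or marrow had a replicate library. In the blood and marrow tests days, tissues or both stood in for replicates, so the spread also holds differences between them. Their n counts libraries of different days or tissues, not replicates. Gene lists, marker sets, comparisons and the rule for which genes to name were chosen before the data were examined. Comparisons of the antibody hearts with WT day 0, of Tet2-labelled with Irf3-/- marrow and of day 2 with day 0 within a genotype, and the progenitor test, were added afterwards. Files of WT blood and marrow at day 0 carried version 3.0.2 and a lowest count of 500 UMIs per barcode, and those after MI carried no version and lowest counts of 948 to 2189. File version and lowest count therefore ran together with MI in WT, while both days of Irf3-/- had 3.0.2 and 500. The antibody heart files also carried no version, with lowest counts of 1145 and 1354 against 500 in both WT hearts. Intervals for single libraries and bounds from a count of 0 cover counting error only.

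The first question was whether transcripts of the targeted genes were low in the libraries labelled as lacking them. Nfe2l2 (ENSMUSG00000015839, chromosome 2, 75675513 to 75704641, mm10), which encodes Nrf2, stood in heart mononuclear phagocytes at 423 CPM (counts per 1e6 UMIs) at WT day 4. It stood at 154 and 172 in the antibody hearts, 31.9 and 29.6 in Nrf2-/- hearts and 337 at WT day 0. In heart neutrophils Nfe2l2 stood at 694, at 118 and 184, at 66.5 and 56.7, and at 859 in the same order. Ifnar1 (ENSMUSG00000022967), a chain of the receptor the antibody binds, stood in mononuclear phagocytes at 105 CPM at WT day 4, 98.6 and 107 with antibody, 103 and 107 in Nrf2-/- and 44.0 at WT day 0. Against WT day 4 its log2 fold change in the antibody hearts was -0.25 (SE 0.15, n = 2 against 1, adjusted p = 0.244).

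Irf3 (ENSMUSG00000003184, chromosome 7, 44997648 to 45002848) stood in blood monocytes at 37.0, 31.8, 33.4 and 41.8 CPM in WT and at 4.99 and 4.86 in Irf3-/-. In marrow monocytes Irf3 stood at 33.0, 31.9 and 35.1 in WT, 7.49 and 6.70 in Irf3-/- and 46.7 and 47.8 in libraries labelled Tet2-/-. In blood neutrophils Irf3 stood at 27.7, 15.1, 16.1 and 18.2 in WT and 2.86 and 9.97 in Irf3-/-, and in marrow neutrophils at 12.2, 11.7 and 11.5 in WT, 1.35 and 1.96 in Irf3-/- and 22.7 and 17.98 in Tet2-/-. Irf3 fell in Irf3-/- against WT with a log2 fold change of -2.91 (SE 0.41, n = 4 against 4, adjusted p = 0.000201) in neutrophils and -2.96 (SE 0.19, n = 4 against 4, adjusted p = 2.2e-06) in monocytes.

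Tet2 (ENSMUSG00000040943, chromosome 3, 133463679 to 133545139) was not low in the libraries labelled Tet2-/-. In marrow monocytes Tet2 stood at 36.0, 20.1 and 29.0 CPM in WT, 99.05 and 91.8 in Irf3-/- and 102 and 68.9 in the Tet2-labelled libraries. In marrow neutrophils Tet2 stood at 15.5, 14.0 and 8.49, at 41.3 and 32.0, and at 41.5 and 26.1 in the same order. Against WT, Tet2 counts rose by 1.28 log2 (SE 0.18, adjusted p = 0.000252) in monocytes and 0.83 (SE 0.19, adjusted p = 0.00578) in neutrophils, and against Irf3-/- of the same barcode set the values were -0.09 and -0.20 (adjusted p = 0.765 and 0.443). These libraries are called Tet2-labelled below.

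Heart cells were then asked how many of each class they held. Mononuclear phagocytes made up 84.1% of cells at WT day 4, 71.5% and 52.1% in the antibody hearts, 76.8% and 77.5% in Nrf2-/- hearts and 45.8% at WT day 0. Neutrophils made up 13.4%, 8.74% and 1.61%, 16.1% and 16.2%, and 1.56%, and conventional dendritic cells 1.76%, 10.8% and 13.8%, 7.07% and 6.22%, and 1.02%. Fibroblasts were 3.16% and 16.8% and endothelial cells 5.53% and 14.7% of antibody hearts, against 0.493% and 0.228% at WT day 4. Unnamed clusters held 48.6% of WT day 0 cells, with markers of endothelial, mural and cardiac muscle cells, and 0.282% and 1.05% of antibody heart cells. The same class was held by different clusters. Mononuclear phagocytes lay mostly in clusters 7, 15 and 9 with antibody, in 0, 3 and 6 at WT day 4, in 11, 3, 0 and 5 in Nrf2-/- and in 21 at WT day 0, and neutrophils in 19 with antibody and in 13 and 14 at WT day 4 and in Nrf2-/-. Cluster 1, led by Cxcl10, Rsad2 and Isg15, held 407 monocyte-like cells and none from the antibody or day 0 hearts.

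With antibody against Ifnar, was the interferon program of heart mononuclear phagocytes lower at day 4 than in WT? Genes that type I interferon switches on fell steeply. Ifit1 (ENSMUSG00000034459), which binds foreign RNA caps, fell by 7.53 log2 (SE 0.23), Ifit3 (ENSMUSG00000074896) by 8.22 (SE 0.68), the antiviral enzyme Rsad2 (ENSMUSG00000020641) by 8.18 (SE 0.24), the ubiquitin-like modifier Isg15 (ENSMUSG00000035692) by 4.50 (SE 0.30), and the T-cell attractant Cxcl10 by 5.73 (SE 0.35), with n = 2 against 1. The regulator Irf7 had a log2 fold change of -4.999 (SE 0.32). Of 44 members of the type I interferon list 43 fell, none rose and 1 was not called. Isg15 stood at 139 CPM at WT day 4 and 7.08 and 7.18 with antibody, Rsad2 at 139 against 0.49 and 0.63, and Ifit3 at 32.5 against 0 and 0.25. Inflammatory mediators fell as well: Osm by 4.68 (SE 0.19), Ccl3 by 3.89 (SE 0.20), Ccl4 by 3.42 (SE 0.21) and the prostaglandin enzyme Ptgs2 by 6.95 (SE 0.43), 17 of 20 members falling. Immediate early genes, which respond to stress and to cell handling, fell by 3.93 (SE 0.27) for Fos, 4.63 (SE 0.22) for Ier3 and 2.75 (SE 0.22) for Junb, 14 of 17 members falling.

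Among interferon-gamma-associated genes 9 of 13 fell, led by the peptide transporter Tap1 at -2.23 (SE 0.14) and the cytokine brake Socs1 at -2.62 (SE 0.19). Cell cycle genes rose for 8 of 17 members, led by the nucleotide enzyme Rrm2 at 2.85 (SE 0.43) and Ube2c at 2.85 (SE 0.52). Outside the lists, the glucocorticoid-induced chaperone Fkbp5 rose by 2.61 (SE 0.31), the matrix protein gene Igfbp7 by 5.08 (SE 1.19) and Lyz1 by 3.19 (SE 0.55), while the nuclear receptors Nr4a2 and Nr4a3 fell by 8.30 (SE 0.21) and 7.23 (SE 0.23). Igfbp7 stood at 1.36 CPM at WT day 4 and 16.96 and 93.58 with antibody, Col1a1 at 1.97, 9.64 and 106.18 and Sparc at 4.81, 19.4 and 122.05, in hearts whose cells were 0.493%, 3.16% and 16.8% fibroblasts. The lysozyme gene Lyz1 was not called without antibody replicate 2. Lsmem1 had no count with antibody and was at least 694-fold lower. The other largest rises were Hist1h2ap (4.57, SE 0.81), Wdr89 (4.26, SE 0.65), the metallothionein Mt2 (3.54, SE 0.86), the ribonucleases Rnaset2a (2.69, SE 0.41) and Rnaset2b (2.41, SE 0.33), Adap2os (2.50, SE 0.27) and Grcc10 (2.08, SE 0.52). Mt2 and Grcc10 were not called without antibody replicate 1 or replicate 2. Largest falls also took in Oas3 (-6.79, SE 0.22), the immediate early gene Fosb (-6.76, SE 0.67) and the neutrophil attractant Cxcl2 (-6.60, SE 0.78).

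The list tests over 13568 genes in 6 mononuclear phagocyte libraries gave a median of -3.57 log2 for the type I interferon list (adjusted p = 3.4e-40 with a preset correlation, adjusted p = 0.63 with an estimated correlation, 44 falling when adjusted over the list alone). Inflammatory cytokines had a median of -3.55 (1.5e-14, adjusted p = 0.63 with an estimated correlation, 17 adjusted over the list alone) and immediate early and heat shock genes -2.75 (6.0e-12, adjusted p = 0.65 with an estimated correlation, 14 adjusted over the list alone). Interferon-gamma-associated genes had -1.85 (8.3e-05, adjusted p = 0.65 with an estimated correlation, 10 adjusted over the list alone) and cell cycle genes 1.98 (8.3e-05, adjusted p = 0.80 with an estimated correlation, 11 adjusted over the list alone). The remaining lists were not called, with medians of -0.40 for MHC class II, -0.55 for NRF2 target, 0.62 for resident cardiac macrophage, 0.07 for repair macrophage, -0.10 for neutrophil granule and -0.31 for stem cell genes. Medians were -0.51 for myeloid, 1.62 for megakaryocyte and erythroid and 0.10 for lymphoid priming, -3.60 for red cell and 1.36 for heart tissue transcripts. In all, 3592 genes were called, 1204 higher and 2388 lower.

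Group and barcode set ran together in that comparison. The antibody hearts shared barcode set A with the WT day 0 heart, and against it Ifit1 fell by 5.30 log2 (SE 0.29), Rsad2 by 5.22 (SE 0.27), Isg15 by 3.72 (SE 0.30), Irf7 by 2.75 (SE 0.34) and Cxcl10 by 4.67 (SE 0.36), with n = 2 against 1. Of the type I interferon list 31 members fell and 1 rose, with a median of -2.36 (adjusted p = 6.3e-27, adjusted p = 0.23 with an estimated correlation, 36 falling and 2 rising when adjusted over the list alone). Ccl3 fell by 4.72 (SE 0.21) and Fos by 5.09 (SE 0.28) against the same heart. That comparison also differed by day and by the 48.6% of unnamed cells, and its 1524 calls became 992 without antibody replicate 1.

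Heart neutrophils were put to the same question. Here Cxcl10 fell by 7.09 log2 (SE 0.88), Rsad2 by 5.79 (SE 0.67), Isg15 by 3.74 (SE 0.63), Irf7 by 3.34 (SE 0.56) and the antiviral synthetase Oas3 by 6.26 (SE 0.62), with n = 2 against 1. Ifit1 and Ifit3 had no count with antibody and were at least 35.7-fold and at least 17.0-fold lower. Inflammatory genes fell for 17 of 20 members, with Ccl4 at -6.28 (SE 0.43), the inflammasome sensor Nlrp3 at -4.82 (SE 0.37) and Ptgs2 at -5.97 (SE 0.51), and Il1a was at least 28.0-fold lower. NRF2 targets fell for 5 of 18 members, among them the cystine transporter Slc7a11 at -5.47 (SE 0.44) and Txnrd1 at -3.37 (SE 0.35). MHC class II genes rose for 3 members, among them H2-Ab1 at 1.83 (SE 0.38). Globin transcripts, which mark red cell RNA, fell, with Hbb-bs at -9.53 (SE 0.56). The largest rises were led by Wdr89 (4.32, SE 0.45) and the glycolytic enzyme Hk2 (2.49, SE 0.47), Fkbp1a (2.44, SE 0.35) and Id2 (2.44, SE 0.49). Tonsl, Rnaset2a, Grcc10, Bloc1s1 and Cfl2 were among them and lost their calls without antibody replicate 1 or 2. The granule gene Camp was at least 60.9-fold lower and Ngp and Ltf fell by 5.79 (SE 0.52) and 4.66 (SE 0.57), while Prtn3 rose by 3.31 (SE 0.87) and gave -0.41 without antibody replicate 1.

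In neutrophils the type I interferon list had a median of -3.11, or -2.79 with 6 members set at their bounds (adjusted p = 3.9e-25, adjusted p = 0.28 with an estimated correlation), 31 of 40 falling and 36 when adjusted over the list alone. Medians were -4.31 for inflammatory cytokines (8.9e-39, adjusted p = 0.17 with an estimated correlation), -2.26 for immediate early and heat shock genes with 12 falling, -0.82 for NRF2 targets, 1.47 for MHC class II and -8.13 for red cell transcripts (adjusted p = 0.28 with an estimated correlation for each of these 4 lists). For neutrophil granule genes the median was 0.09, the mean -1.55 and the test was negative (adjusted p = 0.014, adjusted p = 0.31 with an estimated correlation). Over 9301 genes 1287 were called, 293 higher and 994 lower, and barcode set again ran together with group. The antibody hearts gave few neutrophils, 8.74% and 1.61% of cells.

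Did loss of Nrf2 change heart mononuclear phagocytes at day 4, with all 3 libraries in barcode set B? The targeted gene Nfe2l2 was lower by 3.83 log2 (SE 0.14, n = 2 against 1, adjusted p = 0.0140) and was the only gene called of 13568. Interferon-stimulated genes gave higher values without a call: Isg15 1.29 (SE 0.30, adjusted p = 0.398), Irf7 1.07 (SE 0.30, adjusted p = 0.404), Ifit3 1.06 (SE 0.40, adjusted p = 0.449), Cxcl10 0.86 (SE 0.32, adjusted p = 0.443), Rsad2 0.59 (SE 0.17, adjusted p = 0.414) and Ifit1 0.31 (SE 0.15, adjusted p = 0.497). Isg15 stood at 285 and 413 CPM in Nrf2-/- hearts and 139 in WT. With an unadjusted p under 0.05 there were 1498 genes, and DESeq2 called 106, 54 higher and 52 lower, so that the share of higher genes went from 0% to 50.94%. The single call became 0 without either antibody replicate, 61 without Nrf2-/- replicate 1 and 5 without Nrf2-/- replicate 2.

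As lists, type I interferon genes had a median of 0.34 (adjusted p = 1.7e-07), MHC class II 1.31 (3.1e-11) and interferon-gamma-associated genes 0.53 (6.0e-04) in Nrf2-/- against WT mononuclear phagocytes. NRF2 targets had -0.86 (3.1e-11), red cell transcripts -4.76 (1.7e-07) and heart tissue transcripts -1.80 (2.6e-04). The globin Hbb-bs stood at 26.44 CPM in the single WT day 4 library and 0.14 and 0.84 in Nrf2-/-. It stood at 2.32 and 1.13 with antibody and 207.29 at WT day 0, so its fall was not particular to Nrf2-/-. No member of any of these lists was called, and each list had adjusted p = 0.41 with an estimated correlation. Adjusted over the list alone, 7 NRF2 targets were lower, 6 MHC class II genes higher, 4 red cell transcripts lower and no type I interferon gene was called.

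Neutrophils of the Nrf2-/- hearts gave 20 calls of 9301 genes, 3 higher and 17 lower. Nfe2l2 fell by 3.39 log2 (SE 0.30, n = 2 against 1, adjusted p = 0.000342), and the NRF2 targets Srxn1 and Gclm, which act in peroxide repair and glutathione synthesis, fell by 2.11 (SE 0.32) and 2.03 (SE 0.33). DESeq2 did not call Srxn1 or Gclm. The secreted attractant Prok2 rose by 2.76 (SE 0.33), and the granule genes Ngp and Camp fell by 6.22 (SE 0.38) and 7.46 (SE 0.52). Globins fell, with Hba-a1 at -10.44 (SE 0.53) and Hbb-bs at least 1616-fold lower. Ngp, Camp and globins also fell with antibody, against the same single WT day 4 library. Their falls can therefore lie in that library and were not separated from loss of Nrf2. Isg15 gave 1.05 (SE 0.51, adjusted p = 0.867) and Cxcl10 0.82 (SE 0.44, adjusted p = 0.908).

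The type I interferon list had a median of 0.57 in those neutrophils with no member called (adjusted p = 2.4e-08, adjusted p = 0.24 with an estimated correlation), NRF2 targets -0.83 (2.5e-09, adjusted p = 0.24 with an estimated correlation) and neutrophil granule genes -1.05 (3.4e-24, adjusted p = 0.24 with an estimated correlation). Red cell transcripts had adjusted p = 0.078 with an estimated correlation. The granule and red cell list tests were also negative with antibody against the same single WT library, so neither was particular to Nrf2-/-. The 20 calls became 41 and 33 without antibody replicates 1 and 2, and 130 and 60 without Nrf2-/- replicates 1 and 2. Unadjusted p was under 0.05 for 559 genes.

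Between Nrf2-/- and antibody hearts, all 44 type I interferon genes were higher in Nrf2-/- mononuclear phagocytes, with Ifit1 at 7.85 log2 (SE 0.22), Rsad2 at 8.76 (SE 0.23) and Isg15 at 5.79 (SE 0.29), n = 2 against 2. Ccl3 rose by 5.04 (SE 0.20), Osm by 4.58 (SE 0.18), the vessel growth factor Vegfa by 4.70 (SE 0.37), Tap1 by 2.76 (SE 0.13) and H2-Aa by 1.91 (SE 0.22). The matrix proteoglycan gene Dcn and the muscle gene Tnnt2 fell by 5.40 (SE 0.90) and 2.40 (SE 0.42). The type I interferon median was 4.27 (adjusted p = 3.5e-39, adjusted p = 0.55 with an estimated correlation), and 4665 genes were called, 2608 higher and 2057 lower. That count became 2093 and 2396 without Nrf2-/- replicates 1 and 2. In neutrophils 36 of 40 interferon genes rose, with Rsad2 at 6.36 (SE 0.62) and a list median of 3.36, or 3.27 at the bounds (1.6e-31, adjusted p = 0.39 with an estimated correlation, 39 adjusted over the list alone), among 2037 called genes. Barcode set ran together with group here, and the values within a set are those of Nrf2-/- against WT day 4 and of antibody against WT day 0 given above.

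How did WT mononuclear phagocytes differ between day 4 and steady state? The resident macrophage genes Timd4, Lyve1 and Folr2 were lower by 12.00 (SE 0.93), 9.61 (SE 1.01) and 6.36 (SE 0.66) log2, and Retnla by 13.49 (SE 0.34), with n = 1 against 1 in a fit of 6 libraries. The spread came from the antibody and Nrf2-/- pairs, so these calls hold no measure of variation between WT hearts. The matrix proteoglycan Vcan was higher by 8.13 (SE 0.32), Thbs1 by 6.47 (SE 0.93), Vegfa by 5.39 (SE 0.60) and the matrix protease Mmp14 by 3.40 (SE 0.32). Of the type I interferon list 31 of 44 were called higher, with Oas3 at 5.06 (SE 0.29), Mx1 at 4.19 (SE 0.34), Rsad2 at 2.96 (SE 0.23), Irf7 at 2.25 (SE 0.37) and Ifit1 at 2.24 (SE 0.21). Isg15 gave 0.78 (SE 0.34, adjusted p = 0.145), Ifit3 1.54 (SE 0.52, adjusted p = 0.0856) and Cxcl10 1.06 (SE 0.37, adjusted p = 0.0899). MHC class II genes were lower, with H2-Ab1 at -2.65 (SE 0.27) and Cd74 at -2.63 (SE 0.33), and the NRF2 targets Txnrd1 and Gclc higher by 2.58 (SE 0.27) and 1.75 (SE 0.25). Heart muscle transcripts were lower at day 4, with Myl2 at -6.27 (SE 0.58).

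That test called 3593 genes, 2190 higher and 1403 lower, with an all-gene median of 0.15. Medians were 1.62 for the type I interferon list (adjusted p = 1.1e-13, adjusted p = 0.51 with an estimated correlation, 35 adjusted over the list alone), -5.24 for resident macrophage genes with 10 of 13 lower, -2.63 for MHC class II with 8 lower and 1.45 for repair macrophage genes with 6 of 15 higher and 2 lower (adjusted p = 0.51 with an estimated correlation for each). NRF2 targets had 1.21 with 9 higher and 2 lower (adjusted p = 0.67 with an estimated correlation). Barcode set and infarction ran together, and within set A the antibody day 4 hearts against WT day 0 gave Vcan 6.51 (SE 0.31), Lyve1 -8.52 (SE 0.76), Timd4 -8.64 (SE 0.66), H2-Ab1 -2.98 (SE 0.22) and Mmp14 3.68 (SE 0.30), all called.

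**Figure D1:**
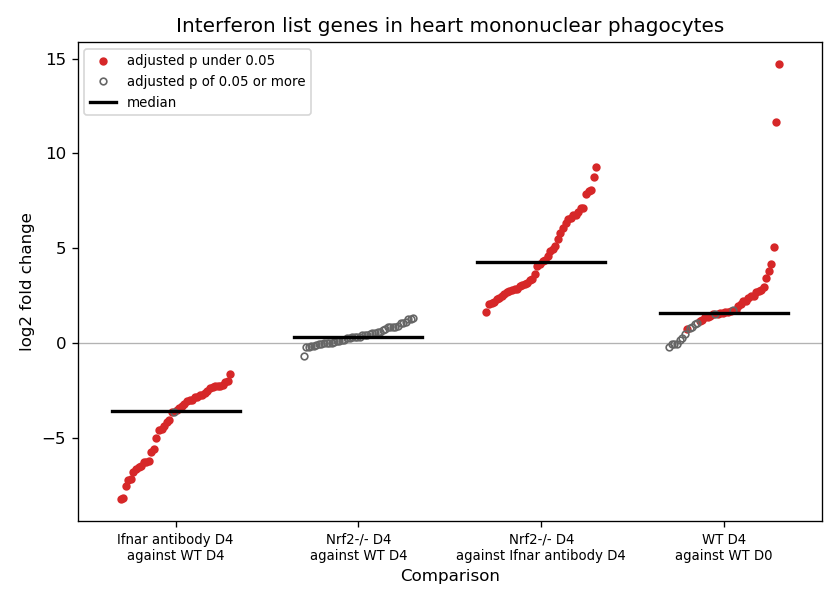
Log2 fold change of each type I interferon list gene (points) in heart mononuclear phagocytes for each comparison on the horizontal axis, with lines at the medians and filled points for adjusted p under 0.05. Fitted values against a group at 0 counts, such as Slfn4 at 14.71 for WT day 4 against day 0 (at least 97.0-fold), are no bound.

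Interferon list UMIs per 10000 UMIs gave the same contrast on the scale of whole libraries. Mononuclear phagocytes held 35.6 at WT day 4, 4.10 and 4.65 with antibody, 49.1 and 41.4 in Nrf2-/- and 11.9 at WT day 0. Against WT day 4 the mean ratio was 0.123 (1 SD from 0.112 to 0.134) with antibody and 1.27 (1.12 to 1.43) in Nrf2-/-. Neutrophils held 41.4, 8.98 and 7.51, 52.2 and 62.5, and 24.8 in the same order. With each cell thinned to 500 UMIs, interferon-high cells, holding at least 3 such UMIs, made up 20.7% of WT day 4 heart cells (median 7186 UMIs). They made up 0.508% and 0.484% with antibody, 29.3% and 24.0% in Nrf2-/- and 6.32% at WT day 0. No B-like or T-like cluster was found in the heart, and among WT day 4 fibroblasts, 52 cells with a median of 1769 UMIs, the share was 3.85%, and among 24 endothelial cells (median 1205 UMIs) 25.0% (9.77% to 46.7%).

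In blood, interferon-high cells made up 13.5%, 8.63%, 12.4% and 15.9% of WT cells at days 0, 1, 2 and 4 and 9.85% and 15.5% of Irf3-/- cells at days 0 and 2. For comparison, at WT day 0 the share was 4.44% of B cells (median 924 UMIs) and 3.28% of T and NK cells (median 960), with a median of 1039 over all cells. In marrow the shares were 3.39%, 1.64% and 6.94% in WT, 6.94% and 4.83% in Irf3-/- and 15.6% and 10.3% in the Tet2-labelled libraries. There, B and T cells had 2.24% (median 1288) and 3.77% (median 2032) at WT day 0, against a median of 2327 over all cells, and 4.40% (median 8530) and 8.64% (median 2613) in the Tet2-labelled day 0 library, against 3308 over all cells. In LSK libraries the share was 2.45% at day 0 and 1.63% at day 1, with 1.59% and 2.52% of B cells.

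**Figure D2:**
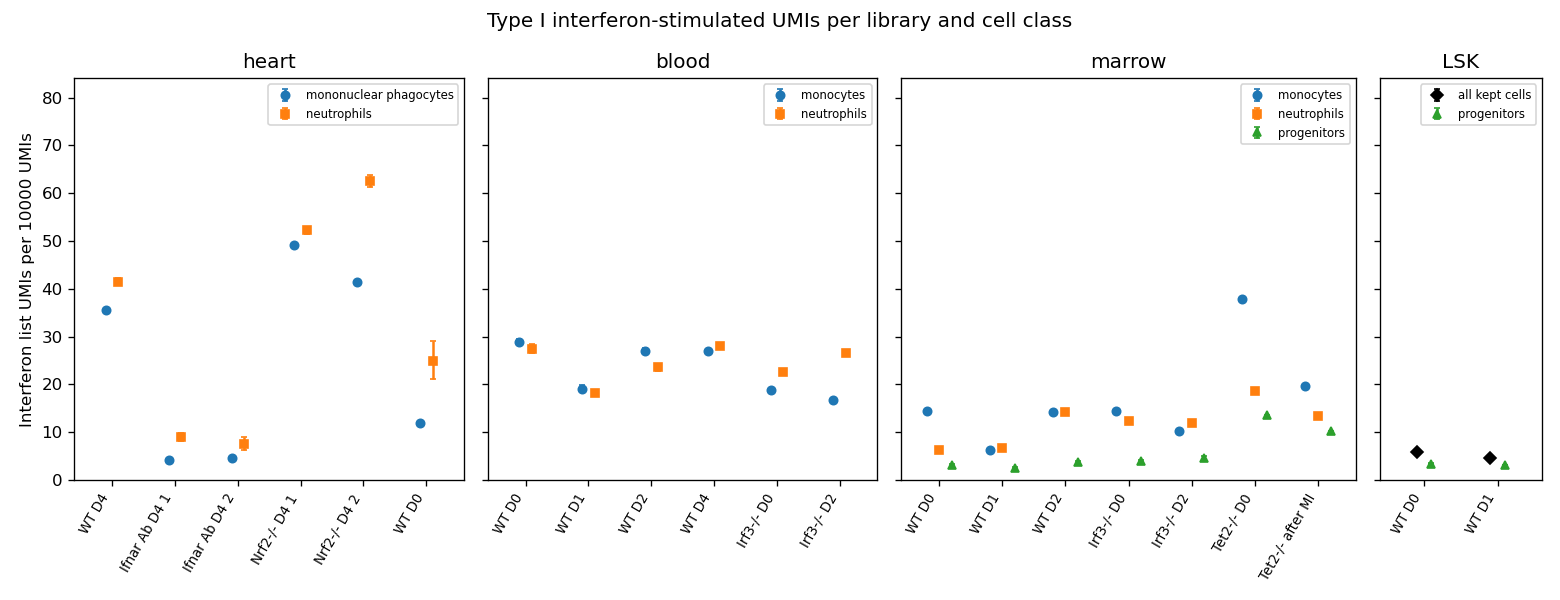
Interferon list UMIs per 10000 UMIs in each library (horizontal axis), by tissue and cell class, with bars for 95% counting intervals. Heart mononuclear phagocytes ran from 4.10 to 49.1.

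Within barcode set A, did MI change interferon genes in WT marrow and blood? Neutrophils gave 9 calls of 8650 genes, 1 higher and 8 lower, in 7 libraries, with n = 5 after MI against 2 at day 0, and file version ran with MI. Days after MI and tissues stood in for replicates in this test and in that of monocytes. The iron reductase Steap4 rose by 2.29 log2 (SE 0.35, adjusted p = 0.0468), the platelet factor Pf4 fell by 4.10 (SE 0.36, adjusted p = 0.00213) and the granule protease Elane fell by 2.61 (SE 0.31, adjusted p = 0.0117). Irf7 gave 0.80 (SE 0.47, adjusted p = 0.460), Cxcl10 1.21 (SE 1.02, adjusted p = 0.612), Ifit3 0.37 (SE 0.67, adjusted p = 0.847), Ifit1 0.31 (SE 0.51, adjusted p = 0.819), Isg15 0.07 (SE 0.42, adjusted p = 0.965) and Rsad2 -0.19 (SE 0.58, adjusted p = 0.917). As a list, type I interferon genes were not called, with a median of 0.15 over 38 members (adjusted p = 0.26, adjusted p = 0.80 with an estimated correlation), and was called without the blood day 0 library (0.38) or the marrow day 1 library (0.34). Without the marrow day 2 library the list median turned to -0.132. Among cells of at least 1000 UMIs and 500 genes the list was called with a median of 0.577. Myeloid priming genes had -0.54 (adjusted p = 0.0096, adjusted p = 0.32 with an estimated correlation) and red cell transcripts -3.48 (1.9e-12, adjusted p = 0.13 with an estimated correlation). Unadjusted p was under 0.05 for 1194 genes, and DESeq2 called 111, 66 higher and 45 lower, so the share of higher genes went from 11.11% to 59.46%. The 9 calls became 5, 30 and 3 without blood day 0, 1 or 2, and 20, 2 and 3 without marrow day 0, 1 or 2. Steap4 was not called without blood day 0 or 2 or marrow day 1 or 2, Pf4 without blood day 0, and Elane without any of the marrow libraries.

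Monocytes gave 30 calls of 9860 genes, 19 higher and 11 lower. Socs3, a feedback brake on cytokine signals, rose by 1.93 log2 (SE 0.30), and the glycolytic genes Aldoa, Pkm and Ldha rose by 1.24 (SE 0.17), 1.18 (SE 0.19) and 1.15 (SE 0.17). The Notch target Hes1 fell by 1.80 (SE 0.25), Irf2bp2 by 1.09 (SE 0.14) and Pf4 by 4.01 (SE 0.52). Cxcl10 gave -2.27 (SE 0.69, adjusted p = 0.118), Rsad2 -1.41 (SE 0.50, adjusted p = 0.157), Isg15 -0.94 (SE 0.48, adjusted p = 0.295) and Irf7 0.07 (SE 0.45, adjusted p = 0.946). The type I interferon list had a median of -0.38 with no member of 43 called (adjusted p = 5.9e-04, adjusted p = 0.51 with an estimated correlation, 2 falling when adjusted over the list alone), and was not called without marrow day 0 (-0.22) or with the day 1 libraries left out (-0.103, unadjusted p = 0.256). Granule genes had 0.57 (adjusted p = 0.015, adjusted p = 0.51 with an estimated correlation). The 30 calls became 3, 0 and 2 without blood day 0, 2 or 4, and 1126, 3 and 4 without marrow day 0, 1 or 2, and every gene named here lost its call without blood day 2.

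Per library, interferon list UMIs per 10000 in blood neutrophils were 27.5, 18.2, 23.6 and 28.0 in WT at days 0, 1, 2 and 4, and in blood monocytes 28.8, 19.1, 27.0 and 26.9. The ratio of day 1 to day 0 was 0.662 in both classes (0.637 to 0.688 in neutrophils). In marrow neutrophils the values were 6.35, 6.75 and 14.2 at days 0, 1 and 2, a ratio of 2.23 (2.14 to 2.32) at day 2, and in marrow monocytes 14.3, 6.21 and 14.3, a ratio of 0.434 at day 1. Neutrophils went from 37.7% of blood cells at day 0 to 88.6%, 57.1% and 66.2%, and NK cells from 12.6% to 0.870%, 3.99% and 4.00%. With cells of at least 1000 UMIs and 500 genes the neutrophil share was 6.468% at blood day 0 and 84.362% at day 1. Marrow B cells went from 18.6% to 4.17% and 1.91%. Each of these values rests on 1 library, without a p-value.

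Did Irf3-/- marrow and blood cells hold lower interferon gene counts than WT? In neutrophils the antiviral synthetase-like Oasl2 fell by 6.04 log2 (SE 0.26), Isg15 by 4.80 (SE 0.30), Ifit3 by 4.35 (SE 0.34), the receptor transporter Rtp4 by 3.20 (SE 0.27), Rsad2 by 2.76 (SE 0.25), Ifit1 by 2.58 (SE 0.31) and Irf7 by 1.04 (SE 0.24), with n = 4 against 4. In monocytes Isg15 fell by 4.66 (SE 0.21), Oasl2 by 4.12 (SE 0.31), the nucleic acid sensor Zbp1 by 2.05 (SE 0.15), Rsad2 by 2.51 (SE 0.22), Ifit3 by 2.47 (SE 0.35), Irf7 by 2.00 (SE 0.20), Ifit1 by 2.06 (SE 0.34) and Cxcl10 by 1.97 (SE 0.47). Of the type I interferon list 20 of 37 fell and none rose in neutrophils, and 29 of 43 fell and 1 rose in monocytes. The classes differed in make-up between the genotypes, as the largest marrow neutrophil cluster was 0 in WT and 27 or 10 in Irf3-/- and the largest blood monocyte cluster 4 in WT and 9 or 21 in Irf3-/-. All 7 MHC class II genes fell in neutrophils, with H2-Ab1 at -3.24 (SE 0.36) and Cd74 at -2.41 (SE 0.28). B cells made up 18.6% and 1.91% of WT marrow at days 0 and 2 and 1.72% and 0.17% in Irf3-/-. In blood they made up 3.14% and 0.969% in WT and 1.26% and 0.39% in Irf3-/-. Ambient RNA was not removed, so class II RNA of other cells in these neutrophil counts was not excluded. The granule protease genes Ctsg, Mpo and Elane fell in monocytes by 2.42 (SE 0.23), 2.22 (SE 0.21) and 2.44 (SE 0.24), and the mitotic gene Ube2c by 1.57 (SE 0.17). The aminopeptidase Lnpep rose by 2.76 (SE 0.19) in neutrophils and the sulfatase Arsb by 2.83 (SE 0.16) in monocytes. BC018473 had no count in these WT libraries and was at least 811-fold higher in neutrophils and at least 1038-fold higher in monocytes. Largest rises in neutrophils also took in Anxa6 (2.53, SE 0.25), Lyst (2.47, SE 0.25), Brd1 (2.25, SE 0.24) and the integrin Itga4 (2.02, SE 0.20), and in monocytes Lilra5 (2.60, SE 0.37), Lyst (2.31, SE 0.22), Brd1 (2.17, SE 0.19) and Dusp16 (2.23, SE 0.32). Falls that were large in both classes were Rnaset2a (-3.79, SE 0.22, and -3.59, SE 0.20), Wdr89 (-3.26, SE 0.40, and -2.93, SE 0.30), the lipid carrier Apoe (-4.56, SE 0.61, and -2.63, SE 0.35) and Ifi27l2a (-2.95, SE 0.24, and -2.58, SE 0.23). The leptin receptor Lepr fell by 6.67 (SE 0.35) in monocytes.

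The type I interferon median was -0.65 in neutrophils (adjusted p = 6.4e-11, adjusted p = 0.71 with an estimated correlation, 20 adjusted over the list alone) and -0.999 in monocytes (2.4e-14, adjusted p = 0.56 with an estimated correlation, 29 falling adjusted over the list alone). MHC class II had -2.52 in neutrophils (3.8e-06, adjusted p = 0.71 with an estimated correlation) and -1.42 in monocytes with 3 falling, and cell cycle genes -0.94 (0.028, adjusted p = 0.86 with an estimated correlation) and -1.20 (3.0e-04, adjusted p = 0.56 with an estimated correlation). There were 3793 calls of 9800 genes in neutrophils, 1900 higher and 1893 lower, which became 2113 without the marrow day 0 block, and 5209 of 10867 in monocytes, 2619 higher and 2590 lower. Irf7 in neutrophils was not called without the marrow day 2 block. The neutrophil interferon list median was -0.422 with the common UMI minimum and -0.987 with no low-count filter. Barcode set B held all Irf3-/- and set A all WT libraries, and no Irf3-/- library had a WT partner in its set. Within set B, Oasl2, Isg15 and Ifit3 of marrow neutrophils were also lower in Irf3-/- than in the Tet2-labelled libraries, as given below.

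List totals and medians differed in places. Blood monocytes held 28.8 interferon list UMIs per 10000 at WT day 0 and 18.8 in Irf3-/-, a ratio of 0.651, and 27.0 and 16.6 at day 2, a ratio of 0.616. Blood neutrophils gave ratios of 0.818 at day 0 and 1.13 at day 2. In marrow day 0 neutrophils the total was higher in Irf3-/- (12.3 against 6.35, ratio 1.94), although the list median of the test was negative. At day 2 marrow neutrophils gave a ratio of 0.847, and marrow monocytes gave 1.01 at day 0 and 0.719 at day 2.

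Did the change after MI differ between Irf3-/- and WT, each followed within its barcode set from day 0 to day 2? File version and lowest UMI count differed between the days in WT and not in Irf3-/-, so this difference was not separated from them. The difference of changes called 0 of the neutrophil genes by edgeR (338 with unadjusted p under 0.05, 7 by DESeq2). In monocytes it called 2 genes, both higher (570 with unadjusted p under 0.05). The matrix proteoglycan Vcan had 6.48 log2 (SE 0.74, adjusted p = 0.0188) and Ctla2a, a protease inhibitor, 4.88 (SE 0.51, adjusted p = 0.0142). DESeq2 called 10, 6 higher and 4 lower, so the share of higher genes went from 100% to 60%. Irf7 gave -0.96 (SE 0.29, adjusted p = 0.887), Ifit3 -1.98 (SE 0.62, adjusted p = 0.903) and Isg15 0.21 (SE 0.43, adjusted p = 0.965) in monocytes. The type I interferon median of the difference was -0.10 in neutrophils (adjusted p = 0.41, adjusted p = 0.94 with an estimated correlation) and -0.38 in monocytes with no member called (7.3e-07, adjusted p = 0.44 with an estimated correlation, 2 falling when adjusted over the list alone). The monocyte median ran from -0.701 without blood WT day 0 to -0.114 without blood WT day 2. The neutrophil median was -0.673 among cells of at least 1000 UMIs and 500 genes and -0.473 with a common UMI minimum (unadjusted p = 1.89e-05 and 7.34e-05). Vcan was not called without blood WT day 0, and Ctla2a was not called without any 1 of the 4 blood libraries, with -1.15 without blood WT day 0.

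Those counts moved with single libraries. The neutrophil 0 became 1 without blood WT day 0, 1 and 6 without blood Irf3-/- day 0 or 2, 66 without marrow WT day 2, and 12 and 47 without marrow Irf3-/- day 0 or 2. Its type I interferon list was called without blood WT day 0 (-0.31), blood WT day 2 (-0.37), blood Irf3-/- day 0 (-0.31) or blood Irf3-/- day 2 (-0.33). Without marrow WT day 0 the median of that list turned to 0.282. The monocyte 2 became 0 without blood WT day 0, 1 without blood Irf3-/- day 2, 72 without marrow WT day 2, and 12 and 4 without marrow Irf3-/- day 0 or 2.

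Within each genotype, the cysteine protease inhibitor Stfa2 rose in neutrophils from day 0 to day 2 by 5.07 log2 (SE 0.59) in Irf3-/-, n = 2 against 2, and the nucleoside enzyme Upp1 by 3.0 (SE 0.28) in Irf3-/- and 2.61 (SE 0.33) in WT. In Irf3-/- neutrophils Thbs1 fell by 4.36 (SE 0.35), Fos by 3.33 (SE 0.44), Atf3 by 3.94 (SE 0.31) and Ptgs2 by 4.81 (SE 0.57). In Irf3-/- monocytes the acute phase gene Saa3 rose by 8.18 (SE 0.55), Vcan by 7.80 (SE 0.62), Lrg1 by 3.94 (SE 0.41), Chil3 by 3.60 (SE 0.34) and Lcn2 by 3.19 (SE 0.51), and the stress gene Ddit4 fell by 2.90 (SE 0.30). Type I interferon medians were 0.45 in WT neutrophils (adjusted p = 1.6e-06, adjusted p = 0.44 with an estimated correlation, 2 adjusted over the list alone), 0.29 in Irf3-/- neutrophils (0.0020, adjusted p = 0.65 with an estimated correlation, 6 adjusted over the list alone), -0.16 in WT monocytes (adjusted p = 0.41) and -0.44 in Irf3-/- monocytes (1.5e-07, adjusted p = 0.48 with an estimated correlation) with 9 of its members falling and 1 rising. That last median was -0.722 without blood Irf3-/- day 0 and -0.227 without marrow Irf3-/- day 0. Among cells of at least 1000 UMIs and 500 genes the WT neutrophil median was 0.874. The interaction value for the monocyte list was -0.38 and for the neutrophil list -0.10. Leaving out libraries ended the WT neutrophil call without marrow WT day 0 (0.02) or day 2 (0.11) and the Irf3-/- neutrophil call without blood Irf3-/- day 0 (0.20) or day 2 (0.08).

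Gene counts from day 0 to day 2 were 12 in WT neutrophils, 7 higher and 5 lower (774 with unadjusted p under 0.05; DESeq2 48, 36 higher and 12 lower, the share of higher genes going from 58.33% to 75%). They were 199 in Irf3-/- neutrophils, 8 in WT monocytes and 379 in Irf3-/- monocytes. The 12 became 38 without blood WT day 2, 32 and 48 without blood Irf3-/- day 0 or 2, 52 without marrow WT day 2, and 45 and 59 without marrow Irf3-/- day 0 or 2. The 199 became 419 and 536 without blood or marrow WT day 2, 77 and 91 without blood Irf3-/- day 0 or 2, and 439 and 740 without marrow Irf3-/- day 0 or 2. The 8 became 0 and 35 without blood WT day 0 or 2, 25 without blood Irf3-/- day 0, 1 and 164 without marrow WT day 0 or 2, and 29 without marrow Irf3-/- day 0. The 379 became 823 and 842 without blood or marrow WT day 2, 119 and 78 without blood Irf3-/- day 0 or 2, and 196 and 90 without marrow Irf3-/- day 0 or 2.

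In marrow, did Tet2-labelled cells hold higher interferon gene counts than WT? Progenitors gave the widest rise. Ifit1 rose by 3.62 log2 (SE 0.48), Irf7 by 2.64 (SE 0.39), Ifi44 by 3.64 (SE 0.40), the RNA sensor Ddx58 by 2.47 (SE 0.26) and Parp14 by 2.77 (SE 0.31), with n = 2 against 3, and 32 of 37 type I interferon genes rose. Isg15 rose by 1.41 (SE 0.42) and was not called without WT day 1 or either Tet2-labelled library. The stem cell genes Ly6a, Meis1 and Hlf rose by 3.54 (SE 0.32), 2.72 (SE 0.27) and 2.94 (SE 0.35), all 9 stem cell members rising, and so did all 7 lymphoid priming genes, with Flt3 at 1.93 (SE 0.26) and Dntt at 3.90 (SE 0.64). The largest progenitor cluster was cluster 19 in each WT library and cluster 15 in both Tet2-labelled ones, so the class differed in make-up. The largest monocyte cluster was 5 in WT and 8 in Tet2-labelled marrow, and the largest neutrophil cluster 0 in WT and 24 or 2 in Tet2-labelled marrow. Myeloid priming genes fell for 9 of 12 members, with Cebpb at -3.24 (SE 0.20), Cebpa at -2.64 (SE 0.25) and Ctsg at -4.22 (SE 0.26), and the cell cycle genes Rrm2 and Cdk1 fell by 2.36 (SE 0.22) and 2.25 (SE 0.21).

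In monocytes Parp14 rose by 2.34 (SE 0.27), Ifit2 by 2.16 (SE 0.32), Rnf213 by 1.80 (SE 0.24) and Cxcl10 by 1.35 (SE 0.30), and 23 of 43 type I interferon genes rose. Isg15 gave 0.45 (SE 0.42, adjusted p = 0.405), Irf7 0.59 (SE 0.35, adjusted p = 0.188), Rsad2 1.03 (SE 0.41, adjusted p = 0.0592) and Ifit3 1.16 (SE 0.47, adjusted p = 0.0609). Ctsg and Mpo fell by 3.30 (SE 0.22) and 2.28 (SE 0.22), and the growth factor receptor Csf1r rose by 1.56 (SE 0.16). In neutrophils Parp14 and Slfn5 rose by 1.63 (SE 0.20) and 2.78 (SE 0.54), 12 of 40 interferon genes rising, and the MHC class II genes Cd74 and H2-Ab1 fell by 2.34 (SE 0.19) and 1.91 (SE 0.28). Isg15 gave -0.49 (SE 0.44, adjusted p = 0.417), Irf7 0.38 (SE 0.43, adjusted p = 0.533) and Ifit1 0.42 (SE 0.43, adjusted p = 0.488) there. B cells made up 2.14% and 0.663% of Tet2-labelled marrow and 18.6%, 4.17% and 1.91% of WT marrow. Class II RNA of other cells in the neutrophil counts was not excluded. Among the largest changes, Brd1 rose by 3.07 (SE 0.17) in neutrophils, 2.97 (SE 0.14) in monocytes and 3.03 (SE 0.20) in progenitors, and the copper chaperone Cox17 fell by 3.21 (SE 0.18), 3.22 (SE 0.14) and 3.65 (SE 0.18). In monocytes Lars2 rose by 3.17 (SE 0.27) and Il10ra by 2.35 (SE 0.18), and Lepr and Rpa3 fell by 4.66 (SE 0.39) and 4.29 (SE 0.20). In neutrophils the cytokine Il1b rose by 2.52 (SE 0.54) and Stfa3 fell by 3.29 (SE 0.80), neither called without the later Tet2-labelled library, and BC100530 fell by 4.70 (SE 0.96). Snhg9 and Rnaset2b fell in progenitors by 6.84 (SE 0.58) and 4.24 (SE 0.41), and H2-Q6, Zbtb20 and Txnip rose by 3.22 (SE 0.24), 3.06 (SE 0.30) and 2.93 (SE 0.30).

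Type I interferon medians were 1.80 in progenitors (adjusted p = 3.4e-10, adjusted p = 0.33 with an estimated correlation, 33 adjusted over the list alone), 1.03 in monocytes (1.1e-06, adjusted p = 0.93 with an estimated correlation) and 0.52 in neutrophils (0.0077, adjusted p = 0.93 with an estimated correlation, 12 adjusted over the list alone). The neutrophil list was not called without the Tet2-labelled day 0 library (0.22). Its median was 0.236 with a common UMI minimum and 1.082 with 4 libraries blocked by day, the later Tet2-labelled one beside WT day 1, against 0.24 beside WT day 2. The same pairings gave 1.409 and 0.672 in monocytes. In progenitors, medians were 2.72 for stem cell genes (9.1e-08, adjusted p = 0.32 with an estimated correlation), 1.93 for lymphoid priming (8.5e-05, adjusted p = 0.33 with an estimated correlation), -2.11 for myeloid priming (7.0e-07, adjusted p = 0.32 with an estimated correlation) and -1.18 for cell cycle genes (1.6e-04, adjusted p = 0.33 with an estimated correlation). Calls numbered 5322 of 10145 genes in progenitors (2678 higher), 5169 of 10922 in monocytes (2566 higher) and 3745 of 11218 in neutrophils (2000 higher). Without the Tet2-labelled day 0 or later library the progenitor count became 3545 and 2635 and the neutrophil count 2249 and 1706. Barcode set and genotype label ran together in all 3 tests, and progenitors made up 18.9% and 18.009% of Tet2-labelled marrow against 6.45%, 6.84% and 6.68% of WT.

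Within barcode set B, Tet2-labelled marrow was compared with Irf3-/- marrow, n = 2 against 2. The largest clusters differed here too, at 8 against 31 in monocytes, 24 or 2 against 27 or 10 in neutrophils and 15 against 19 in progenitors. In monocytes Oasl2 was higher by 5.26 log2 (SE 0.54), Isg15 by 4.92 (SE 0.55), Ifit1 by 2.45 (SE 0.36), Irf7 by 2.33 (SE 0.38), Rsad2 by 2.90 (SE 0.42) and Cxcl10 by 1.72 (SE 0.27), 37 of 43 interferon genes rising, with Tap1 at 1.72 (SE 0.16). In neutrophils Oasl2 rose by 7.69 (SE 0.57), Isg15 by 4.47 (SE 0.54), Ifit3 by 4.44 (SE 0.56) and Ifit1 by 3.08 (SE 0.45), 23 of 40 rising. In progenitors Ifit1 rose by 5.85 (SE 0.66), Oasl2 by 5.73 (SE 0.70), Isg15 by 4.87 (SE 0.69), Irf7 by 4.32 (SE 0.53), Ly6a by 3.93 (SE 0.37), Flt3 by 2.71 (SE 0.31) and Il7r by 4.65 (SE 0.61). Cebpb fell by 3.34 (SE 0.20) and Ctsg by 2.93 (SE 0.25) there, while BC018473 was at least 14463-fold lower.

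The interferon list median in that comparison was 1.58 in monocytes (adjusted p = 1.6e-26, adjusted p = 0.46 with an estimated correlation, 41 adjusted over the list alone), 1.13 in neutrophils (4.0e-12, adjusted p = 0.75 with an estimated correlation, 27 adjusted over the list alone) and 1.76 in progenitors (9.3e-10, adjusted p = 0.35 with an estimated correlation, 27 adjusted over the list alone). Calls numbered 2326 in monocytes, 2474 in neutrophils and 4029 in progenitors. The monocyte count became 1246 and 582 without Irf3-/- day 0 or 2 and 698 without the later Tet2-labelled library. The neutrophil count became 783 and 660 without Irf3-/- day 0 or 2, and 1165 and 550 without the Tet2-labelled day 0 or later library. For progenitors the counts were 2312, 1976, 1612 and 2134 in the same order. The Irf3-/- libraries are no WT control, so a difference can lie in either genotype.

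Interferon list UMIs per 10000 in Tet2-labelled marrow were 18.5 and 13.4 in neutrophils, 37.8 and 19.6 in monocytes and 13.5 and 10.2 in progenitors, at day 0 and after MI. At WT day 0 they were 6.35, 14.3 and 3.02, giving day 0 ratios of 2.92, 2.64 and 4.47. After MI the values were lower than at day 0, with ratios of 0.724, 0.519 and 0.753, from 1 library each and without a p-value.

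For LSK cells, the question was whether interferon and lineage genes differed a day after MI, with 1 library at each time and no p-value. The kinase gene Pim1 stood at 2.93 times its day 0 level (2.76 to 3.11), the granule genes Ltf and Lcn2 at 2.36 and 2.30, the class I gene H2-Q7 at 2.20, Mmp9 at 2.17 and Mif at 1.92. Wdr89 (3.40), Wfdc21 (2.05), Dmkn (2.02) and Snhg9 (1.97) were the other largest rises. Isg15 stood at 0.637 (0.558 to 0.726), Irf7 at 0.502, Cxcl10 at 0.382, Ifit3 at 0.323, Rsad2 at 0.721 and Ifit1 at 1.17 (0.845 to 1.65). In progenitor-like cells Isg15 stood at 0.794 (0.603 to 1.051), Irf7 at 0.423 (0.245 to 0.73) and Cxcl10 at 0.703 (0.296 to 1.75). Ifit3 stood there at 1.094 (0.25 to 6.555), Rsad2 at 1.234 (0.715 to 2.216) and Ifit1 at 1.195 (0.7 to 2.117). Over all cells globin transcripts were lower, with Hba-a2 at 0.067 and Hbb-bs at 0.080, and Hba-a2 at 0.353 among cells of at least 1000 UMIs. Further low ratios were Hist1h2ap 0.073, Gstp1 0.075, Erdr1 0.115, Erh 0.256 and Dynlt1f 0.285. Of 44 type I interferon genes 35 were lower and 9 higher, with a median of -0.34 log2, below all 10000 random lists of like expression. Random lists were drawn gene by gene, so percentiles among them take no account of genes that vary together. Interferon list UMIs were 5.83 and 4.62 per 10000, a ratio of 0.792 (0.778 to 0.807), and 0.921 (0.888 to 0.955) in progenitor-like, 1.26 in neutrophil-like and 0.667 in monocyte-like cells.

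Among the other LSK lists, medians (with percentiles among random lists) were 0.52 for immediate early and heat shock genes (100), 0.34 for interferon-gamma-associated genes (99.74), 0.29 for neutrophil granule genes (99.6), 0.33 for lymphoid priming (98.36) and 0.28 for stem cell genes (98.24). Myeloid priming had -0.16 (1.81), megakaryocyte and erythroid priming -0.37 (0.01) and red cell transcripts -3.08 (0). MHC class II, NRF2 target and cell cycle genes lay at -0.01, -0.03 and -0.01, and MHC class II at -0.239 (0.33) with all 8 members lower among cells of at least 1000 UMIs and 500 genes. Progenitor-like cells made up 33.8% and 31.6% of the LSK libraries, monocyte-like cells 37.4% and 25.1%, neutrophil-like cells 10.1% and 17.2%, B cells 2.53% and 7.17% and unnamed clusters 9.01% and 8.34%. The LSK libraries were thus mixed in class by these markers. In their progenitor-like cells Ly6a, which encodes Sca-1, stood at 5.93 and 11.33 CPM at days 0 and 1. In WT marrow progenitors Ly6a stood at 10.74, 8.47 and 8.13 at days 0, 1 and 2, so it was not clearly enriched. Within progenitor-like clusters the medians were -0.07 (5.74) for neutrophil granule genes, 0.00 (22.28) for lymphoid priming and 0.06 (56.35) for stem cell genes. They were 0.48 (100) for immediate early and heat shock genes, 0.37 (99.94) for interferon-gamma-associated genes, -0.16 (0.48) for type I interferon genes and -0.70 (0) for megakaryocyte and erythroid priming there.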

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

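The difference of changes was planned, and so were its settings apart from the common UMI minimum. The stress test and both correlations of 0.597 and 0.605 across genes were fixed before their values were known. The other tests of explanations below were chosen only after the result was seen.

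Several values stood apart. In monocytes the interferon list's change after MI had a median difference of -0.376 log2 between Irf3-/- and WT (adjusted p = 0.44 with an estimated correlation) and no member called. Ctla2a (4.88) and Vcan (6.48) were the only genes called there with edgeR and the count filter, against 10 by DESeq2 and 122 with no low-count filter. Ctla2a was not called without any 1 of the 4 blood libraries, and the list median ran from -0.701 to -0.114 with 1 library left out. Conventional dendritic cells of the Nrf2-/- hearts, a class no test had been planned for, held 45.562 and 32.374 interferon list UMIs per 10000. The cause of these values was not tested.

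The lower interferon list in mononuclear phagocytes of the antibody hearts could come from the barcode set, from other proportions of monocytes and macrophages, or from a lower stress response. Against the WT day 0 heart, which shares their barcode set, the list median was -2.36, which argues against the barcode set as the only cause, although file version and lowest UMI count differed there. Over macrophage-like clusters alone it was -3.44, which argues against the proportions of monocyte-like to macrophage-like cells. Those clusters were mostly 7, 9 and 12 or 10 with antibody and 3, 8 and 5 at WT day 4. Another mixture within the macrophage-like class was therefore not excluded. In the WT day 4 cells lowest in immediate early and heat shock UMIs (a fraction of 0.25) the list still held 29.39 per 10000. Those cells held 72.02 stress UMIs per 10000 against 31.41 and 26.42 in the antibody hearts, so the stress explanation is undecided.

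For the large number of genes called between Irf3-/- and WT, a difference between barcode sets is a likely part. Across genes, Irf3-/- minus WT in blood and Tet2-labelled minus WT in marrow, which share no library, had r = 0.597 in neutrophils and r = 0.605 in monocytes, which goes with the barcode set or what runs with it. Within set B, Irf3-/- minus Tet2-labelled in marrow had r = 0.394 and 0.361 with the same blood difference, which goes with genotype. Of 27 interferon genes in neutrophils 15 were lower in Irf3-/- blood, 24 in marrow and 15 in both. Of 37 in monocytes the counts were 29, 36 and 28. With so many lower in marrow, where the Tet2-labelled list was higher than in WT, this overlap does not decide between genotype and barcode set. Of the 32 splits of the 8 libraries that were fitted, only the real one, 1 split, gave 3793 calls in neutrophils and 5209 in monocytes, and the highest other gave 0. Only 8 of these splits kept the libraries paired by tissue and day as the real one did, too few for a share under 0.05, and the real split is also the split by barcode set.

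Against WT, the monocyte interferon list was lower in Irf3-/- with blood and marrow fitted together and higher in Tet2-labelled marrow, while list UMIs of marrow day 0 monocytes gave Irf3-/- over WT of 1.013. Between these genotypes in marrow, both in set B, the median was 1.58, which mostly restates that pattern and is no new test. Their largest monocyte clusters differed (31 in Irf3-/- and 8 in Tet2-labelled marrow), so another mixture within the class was not excluded. Against WT the Tet2-labelled median was 1.03, and whether 1 genotype changed and the barcode set moved the other could not be told apart. The direction in each genotype against WT is therefore possibly shifted by an unknown amount.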

How the results depend on the processing

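Alternatives chosen only after the result was seen were the common UMI minimum, the tests within barcode set B, macrophage-like clusters for WT day 0, the day 0 to day 2 tests, the removal of day 1 libraries and of doublets in the interferon share. Other settings kept 168 of 199 gene counts, 169 of 175 interferon list medians and 6419 of 6601 named gene values. Of 2339 values without a test, such as shares and ratios, 1523 were kept, 815 moved and 1 turned. A count was kept within 1.5 times, and a median or named gene with the same sign and call, whatever its size. The call of a median was that at the preset correlation, and the estimated correlation was not among the settings counted. With an estimated correlation, none of the type I interferon lists called above kept its call. A share or ratio was kept inside the interval of its main value. No scaling moved the median over all genes by more than 0.1. Leaving out 1 library kept 76 of 150 counts, 128 of 150 medians and 4243 of 4674 named gene values. Named values and ratios that turned were Prtn3 in neutrophils, antibody against WT day 4 (-0.41 and 3.92 without antibody replicates 1 and 2), Ctla2a in monocytes without blood WT day 0 (-1.15 for the difference of changes and 0.9 for WT, against 5.67 and -5.91 without blood WT day 2) and the Irf3-/- marrow neutrophil ratio of day 2 to day 0 (1.015 with the common UMI minimum). Interferon list medians that turned with 1 library left out were those of MI in neutrophils, the neutrophil difference of changes and WT monocytes from day 0 to day 2, given below. The median for antibody against WT day 4 ran from -3.675 to -3.493 in mononuclear phagocytes and from -3.546 to -2.829 in neutrophils with single libraries left out.

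DESeq2 called 106 genes for Nrf2-/- against WT mononuclear phagocytes, 775 and 1285 in heart neutrophils for antibody against WT day 4 and Nrf2-/- against antibody, 111 and 268 for MI in neutrophils and monocytes, 7 and 10 for the difference of changes, and 48 and 89 for WT from day 0 to day 2. Without a low-count filter the counts were 23 and 160 for Nrf2-/- against WT in mononuclear phagocytes and neutrophils, 14 and 397 for MI, 55 and 122 for the difference of changes, 108 and 285 for WT and 613 and 834 for Irf3-/- from day 0 to day 2. Macrophage-like clusters only gave 999 for antibody against WT day 0, and barcode set B only gave 48 for Nrf2-/- neutrophils.

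With at least 1000 UMIs and 500 genes the MI list median in neutrophils was 0.577, the difference of changes 3 calls and -0.673, the WT day 2 count 26, the WT marrow neutrophil ratio 2.812, the LSK ratio 0.777 and median -0.344, and blood neutrophils 6.468% and 84.362% at days 0 and 1. The common UMI minimum gave 0.582, 1 call and -0.473 and a ratio of 3.065 for the same results. With day 1 libraries left out the MI counts were 40 and 12 and the medians 0.415 and -0.103, the second no longer called. At most 5% mitochondrial UMIs gave 18 for MI and 5 for WT day 2 in monocytes, and days 1 and 2 only gave 2. With doublets removed the WT day 2 counts were 19 and 5 and the Tet2-labelled monocyte ratio 2.795. The gap in interferon-high cells among heart mononuclear phagocytes was 33.4 points with at least 2 UMIs, 38.92 thinned to 1000 and 67.69 not thinned. TMM scaling gave -0.413 for LSK.

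Leaving out 1 library at a time gave 0 to 61 calls for Nrf2-/- against WT, 2093 to 4619 for Nrf2-/- against antibody and 992 to 1955 for antibody against WT day 0 in mononuclear phagocytes, and 33 to 130 for Nrf2-/- against WT in neutrophils. MI gave 2 to 30 with medians of -0.132 to 0.384 in neutrophils and 0 to 1126 with -0.657 to -0.184 in monocytes. Irf3-/- against WT in neutrophils gave 2113 to 3834. The difference of changes gave 0 to 66 with -0.37 to 0.282 in neutrophils and 0 to 72 with -0.701 to -0.114 in monocytes. From day 0 to day 2 neutrophils gave 8 to 59 with 0.021 to 0.887 in WT and 77 to 740 with 0.078 to 0.677 in Irf3-/-, and monocytes 0 to 164 with -0.259 to 0.135 in WT and 78 to 842 with -0.722 to -0.227 in Irf3-/-. Tet2-labelled against WT gave 1706 to 3472 with 0.223 to 1.064 in neutrophils and 2635 to 6038 in progenitors, and against Irf3-/- 550 to 3258, 582 to 2600 and 1612 to 5610.

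With replicate number as a block, Nrf2-/- against antibody gave 3892 calls in mononuclear phagocytes and 1577 in neutrophils, and the labels do not show that replicates were paired. Ambient RNA removal and integration across libraries were not run. At these depths a 2-fold change was found for few genes in the heart tests, so a missing call there is no evidence of no change.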

Other observations

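Every value in this part was chosen only after the result was seen, apart from both correlations across genes.

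Conventional dendritic cells of the heart held 28.0 interferon list UMIs per 10000 at WT day 4, 4.94 and 5.52 with antibody, 45.6 and 32.4 in Nrf2-/- and 9.67 at WT day 0. Relative to WT day 4 the mean ratio was 0.187 with antibody and 1.39 in Nrf2-/- hearts. Heart fibroblasts held 13.5 at WT day 4, 1.88 and 2.82 with antibody and 8.05 at day 0. In marrow, T cells held 11.8 at WT day 0 and 20.017 in Irf3-/- day 0, and plasmacytoid dendritic cells 15.3, 15.3 and 18.8 in WT at days 0, 1 and 2. B cells of WT marrow held 7.38, 6.24 and 12.5.

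In Irf3-/- libraries BC018473 (ENSMUSG00000056032, chromosome 11) stood at 1150 and 944 CPM in marrow progenitors and at 0, 0.47 and 0 in WT marrow at days 0, 1 and 2 and at 0 in both Tet2-labelled libraries. Bcl2l12, whose gene overlaps that of Irf3 on chromosome 7, stood in blood monocytes at 2.62 and 2.71 CPM in Irf3-/- and at 10.3 to 20.2 in WT. The cause of either value was not tested.

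Some genes with large differences could follow the barcode set or the counting of repeated sequences more than biology, among them Rnaset2a and Rnaset2b. For genes over 2-fold apart in blood between Irf3-/- and WT, the sign was the same in marrow between Tet2-labelled and WT for 93.53% in neutrophils, where r was 0.597, and 92.99% in monocytes, where r was 0.605. A design with WT and each genotype in the same barcode set, and with more than 1 WT heart at day 4, would separate these causes.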
